A study of Mus musculus with 20 samples.

How the data were processed

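Expression was measured in 11 MEF and 9 ESC samples on 20 Illumina bead arrays. Per the file headers, the deposited non-normalized table gives for each probe and array a mean bead signal (an intensity on a linear scale), a detection p-value against negative control beads, and a bead count. The deposited series matrix holds intensity values that the authors had normalized between arrays on the linear scale. The submitters' processing notes name BeadStudio and limma, with no version and no model. In the series matrix 19 of 20 columns shared one set of sorted values within 2%, and the column of MEF hom 3 differed from it by up to 9.22%. Arrays were therefore analysed from the non-normalized signal, and the series matrix served as an alternative.

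Samples were grouped by cell type and genotype as labelled, with 4 wt, 4 het and 3 hom MEF arrays and 3 ESC arrays per genotype. All columns matched a sample. In R 4.3.3 with limma 3.58.1, background was corrected with neqc, which infers the negative control signal from the detection p-value (936 control beads implied), with an offset of 16, and arrays were quantile normalized within each cell type. Probes with a detection p under 0.01 on at least 3 arrays of the cell type were tested: 15125 probes of 8999 genes in MEF (8 residual degrees of freedom) and 14502 of 8694 genes in ESC (6). Each cell type was fitted as 1 factor of 3 groups with lmFit and eBayes with a trend, and adjusted p is Benjamini-Hochberg over the probes tested, with a threshold of 0.05. Interactions between genotype and cell type, and the wild-type ESC against MEF comparison, came from all 20 arrays normalized together (17067 probes, 14 residual degrees of freedom). Of 45281 probes, 34885 matched 1 gene, 18 several and 10378 none. Figures were drawn with matplotlib 3.10.9.

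The choice of tests, thresholds, alternatives, 38 gene lists and the rule for naming genes was made before the data were examined, except where an alternative or test is said to have been chosen after. Lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with 1 probe per gene, adjusted over the lists of a comparison. An estimated correlation was the alternative. Counts adjusted over the list alone used the p of the list's members only. Named genes were Mysm1, the 12 largest rises and 12 largest falls past the threshold with no overlap between groups in hom against wt, and 5 and 5 in other comparisons. Where fewer passed, all that passed were named, and where none passed, the 3 with the smallest p, with each gene read by its probe with the highest mean. In fits with the replicate block, a change in the same direction in every replicate pair took the place of no overlap, and in the fit with the first principal component overlap was not asked. These forms depart from the rule set beforehand and were chosen after the pairing and the component were seen. Up to 4 members of a list were named by smallest p. A gene not above background on any array of one group is given as a bound, the mean of the brighter group over the mean of, per array, the higher of the lowest detected signal and the probe's own. Mysm1 was also compared with an exact two-sided permutation test. Xlr4a, Eif2s3y and chromosomes X and 8 were singled out, for single arrays, after their values were seen.

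Whether equal replicate numbers pair samples across genotypes was checked by correlating arrays after removal of group means. In ESC 9 of 9 arrays were closest to an array with their own number, and in MEF 3 of 11 were, so fits with the replicate block (4 residual degrees of freedom) are given for ESC as well. Chromosome medians used genes with a mean log2 intensity of at least 7 and were set against 10000 random gene lists. Alternatives covered background correction, normalization, the series matrix, the filter on dim probes, slide as a fixed or random block and within slides, the replicate block, array weights, eBayes without a trend, stricter thresholds and leaving out each replicate. Without the libraries labelled het 1 and hom 1, and with principal components as covariates, alternatives were added after seeing the data. The method was tested on simulated data with 200 changed probes: at log2 changes of 0.5, 1, 2 and 3, MEF hom against wt recovered 6, 40, 78 and 94% of them, with 7 false calls among 117. ESC hom against wt recovered 16, 50, 88 and 94% with 7 false calls among 134, and 22, 84, 100 and 100% with 13 false calls among 175 with the replicate block, shares of false calls above the 0.05 set in each case. Simulated errors were drawn independently for each probe and array. The real arrays shared structure across probes that crossed genotype, so these shares need not hold for them.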

Results

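Gene expression was measured with Illumina bead arrays of 45281 probes in 20 samples of mouse cells. The cells were embryonic fibroblasts (MEF), which are mesenchymal cells grown from embryos, and embryonic stem cells (ESC). Samples were wild type (wt), heterozygous (het) or homozygous (hom) for the tm1a allele of Mysm1, which encodes a deubiquitinase of histone H2A. There were 4 wt, 4 het and 3 hom MEF arrays, and 3 ESC arrays of each genotype. Median raw signal was 53.2 to 59.95 on 19 arrays and 95.7 on the array of MEF hom 3. The percentage of probes detected was 28.5 to 31.8, and the mean number of beads per probe was 42.5 to 45.5. The number of arrays limits the precision. ESC samples of a genotype were passages, and how many lines they came from was not stated, so their p-values may measure only the spread between these samples.

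Arrays lay on 5 slides, and within a cell type no slide held both wt and hom. The first principal component held 68.0% of the variance among MEF arrays and parted wt 2, wt 3, het 3, het 4 and hom 3 from the other 6 arrays, which also included every genotype. The first component of ESC arrays held 42.9%. The most alike pair of ESC arrays was that labelled het 1 and hom 1, with r = 0.993 across probes.

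Cell identity genes followed the labels. Of 28 naive pluripotency genes tested, 27 rose in wild-type ESC against wild-type MEF, with a list median of 4.64 on the log2 scale, or 4.07 with members below background in one group at their bound. Pou5f1, a core pluripotency factor, was at least 64.3-fold higher and Nanog at least 27.4-fold (limma adjusted p = 3.60e-14 and 1.38e-15, n = 3 and 4), as neither was above background on any wild-type MEF array. Of 28 fibroblast and extracellular matrix genes, 27 fell, with a median of −3.43, among them the collagen gene Col1a1 at −5.00 ± 0.703 (SE). In limma, 9599 of 17067 probes differed between the wild-type groups, 5191 higher and 4408 lower in ESC.

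The level of Mysm1 shows how far the allele lowered its transcript. Of 4 Mysm1 probes, 1 was above background (ILMN_3119954), on 17 of 20 arrays. In MEF its log2 intensity was 7.33 ± 0.24 in wt (SD, n = 4), 6.50 ± 0.16 in het (n = 4) and 5.27 ± 0.25 in hom (n = 3, detected on 2). Mysm1 fell by 2.06 ± 0.184 (SE) in hom against wt MEF, to a measured 24.0% of the wild-type level (limma adjusted p = 0.00465). Background and the offset of 16 compress dim values, and hom 3 (4.98) was not above background, so the share of transcript left can be lower than measured, here and in het. The exact two-sided permutation p was 0.0571, the smallest this design allows. In het MEF it stood at 56.1% of wild type (−0.83 ± 0.170, adjusted p = 1.00 over all probes, exact permutation p = 0.0286, again the smallest possible). Hom against het MEF gave −1.23 ± 0.184 (adjusted p = 0.309, exact permutation p = 0.0571). The fall in hom MEF missed the threshold in limma when all 20 arrays were normalized together, with slide as a block and with the replicate number as a block. Over 21 alternatives its adjusted p ranged from 1.40e-05 to 0.465.

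In ESC, Mysm1 was 7.60 ± 0.11 in wt, 5.94 ± 1.29 in het and 5.57 ± 0.84 in hom (SD, n = 3 each). Single wt arrays lay at 7.69, 7.48 and 7.64. The library labelled het 1 lay at 4.45, where the probe was not detected, against 6.68 and 6.67 in het 2 and het 3. The library labelled hom 1 lay at 6.47, against 5.42 and 4.81 in hom 2 and hom 3. Hom against wt gave −2.04 ± 0.570 (limma adjusted p = 0.297, and 0.0460 with the replicate block), and het against wt −1.67 (adjusted p = 0.952, blocked 0.187). Hom against het gave −0.37 (adjusted p = 0.995, blocked 0.803), which ran from −1.12 without the library labelled het 1 to 0.0110 without hom 3. The exact two-sided permutation p was 0.1, 0.1 and 0.8 in that order, where 0.1 is the smallest possible. Without the libraries labelled het 1 and hom 1, an alternative chosen after seeing the data and in part from these Mysm1 values, so that its p-values for Mysm1 are no test of the order of genotypes, the blocked differences in limma were −2.46 for hom against wt (adjusted p = 3.15e-05), −0.88 for het against wt (adjusted p = 0.0300) and −1.58 for hom against het (adjusted p = 0.00316). Adjusted p over all alternatives ran from 3.15e-05 to 0.653, from 0.00120 to 1.00 and from 0.00316 to 1.00.

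**Figure D1:**
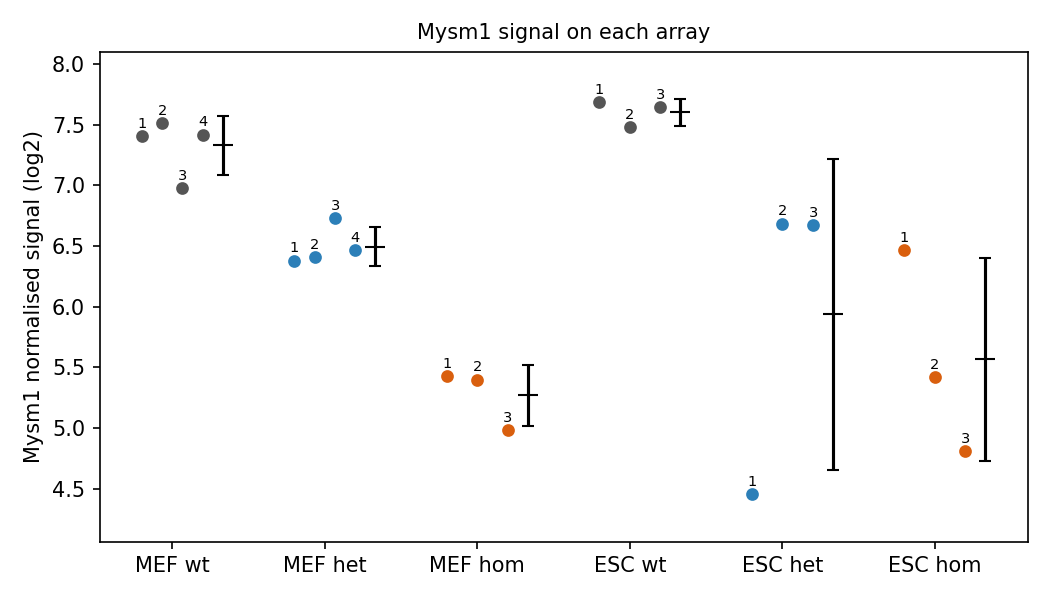
Log2 intensity of the Mysm1 probe on each array by cell type and genotype, with points numbered by replicate and bars for the mean and SD. The library labelled ESC het 1, at 4.45, lies below every hom array, and that labelled hom 1, at 6.47, lies near het 2 and het 3 at 6.68 and 6.67.

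The comparison of hom with wt MEF asks what loss of Mysm1 does to fibroblast expression. Interferon response genes were lower in hom MEF: 22 of 22 measured members were negative, with a median of −0.87 (n = 3 hom and 4 wt). The list fell relative to other genes (camera adjusted p = 5.59e-19, adjusted p = 0.284 with an estimated correlation). Among members were Oasl2 at −1.95 ± 0.70 (SE) and Isg15, a ubiquitin-like modifier, at −2.38 ± 0.87. Rsad2 and Oasl1, not above background on any hom array, were at least 1.92-fold and 1.25-fold lower (adjusted p = 0.999 each over all probes). Of 19 genes of inflammatory secretion, 17 were negative, with a median of −0.95 (adjusted p = 1.93e-12, adjusted p = 0.244 with an estimated correlation). They included the chemokine gene Ccl7 at −1.56 ± 0.56, with Lcn2 at least 2.81-fold and Ccl5 at least 1.42-fold lower (adjusted p = 0.999 each over all probes), as neither was above background on any hom array. With such members at their bound the medians of the 2 lists were −0.70 and −0.74. No member of either list passed over all genes or adjusted over the list alone.

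Glycolysis and hypoxia genes were negative in 19 of 20 cases, with a median of −0.27 (adjusted p = 4.49e-06, adjusted p = 0.443 with an estimated correlation). Adjusted over the list alone, 1 of them fell, Pdk1, the pyruvate dehydrogenase kinase, at −0.54 ± 0.14. MHC class I genes were negative in 6 of 8 cases (median −0.45, adjusted p = 0.0149, adjusted p = 0.506 with an estimated correlation), and 2 fell adjusted over the list alone, H2-D1 at −1.14 ± 0.37 and H2-K1, at least 1.3-fold lower as it was not above background on any hom array. With bounds the MHC class I median was −0.37 and that of macrophage genes, described next, −0.25. Macrophage genes were negative in 16 of 16 cases (median −0.31, adjusted p = 0.0149, estimated correlation adjusted p = 0.727). Their median lay 1.08 and 0.81 above the wt mean in wt 1 and wt 4 and −1.11 and −0.74 from it in wt 2 and wt 3, and with slide as a block, which links hom to wt through het 4 alone, the list was higher in hom, at a median of 1.27. S phase genes (21 of 24 negative, median −0.15, adjusted p = 0.00864) and immediate early genes (14 of 16 negative, median −0.31, adjusted p = 0.0196) were lower as lists, each with adjusted p = 0.727 with an estimated correlation. Without wt 3 the median was 0.00101 for S phase genes and −0.13 for immediate early genes, without wt 1 it was 0.0669 for macrophage genes, without wt 2 −0.14 for glycolysis genes, and without hom 3 −0.54 for interferon and −0.24 for MHC class I genes.

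Cartilage and bone genes were positive in 9 of 9 cases in hom MEF, with a median of 0.77 (adjusted p = 0.000333, adjusted p = 0.244 with an estimated correlation). Among them were the cartilage collagen genes Col9a2 at 1.00 ± 0.45 and Col2a1 at 1.41 ± 0.91, and Col11a1, at least 1.05-fold higher as it was not above background on any wt array. Cholesterol biosynthesis genes were positive in 16 of 17 cases, with a median of 0.39 (adjusted p = 0.00160, adjusted p = 0.727 with an estimated correlation), Cyp51 at 0.63 ± 0.39 among them. Smaller positive medians were those of imprinted genes at 0.21 (15 of 18, adjusted p = 0.0308, Dlk1 at 0.40 ± 0.14), p53 targets at 0.19 (18 of 23, adjusted p = 0.0245, Dcxr at 0.83 ± 0.25) and fibroblast and extracellular matrix genes at 0.18 (23 of 28, adjusted p = 0.0410). These last 3 lists had adjusted p = 0.727 with an estimated correlation. Without wt 3 the medians of the cholesterol, imprinted and fibroblast lists were 0.25, 0.0758 and 0.0794, and without hom 3 those of p53 targets and cartilage genes were 0.0744 and 0.51. Cytosolic ribosomal proteins (53 genes, median −0.02, adjusted p = 0.348), histone H2A ubiquitin ligases and deubiquitinases (25 genes, median 0.04, adjusted p = 0.735), Hox genes (adjusted p = 0.348) and neighbours of Mysm1 (6 genes, adjusted p = 0.891) did not pass.

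Of 15125 probes tested in MEF hom against wt, 1 fell in limma, that of Mysm1, and 0 rose, with 387 at an unadjusted p under 0.05. That share is below the 0.05 that chance gives. So were those of the other MEF comparisons, and of het against wt and hom against het ESC, in fits of genotype alone. Of 32 lists, 12 passed, 5 higher and 7 lower, and 0 passed with an estimated correlation. When slide was a block 0 probes passed in limma (2241 at an unadjusted p under 0.05) and 14 lists did, 0 of them with an estimated correlation. No slide held both groups. With the first principal component as a covariate, chosen after seeing the data, 4 probes fell, those of Mysm1, Lgals3 (galectin 3, −0.68 ± 0.0742, adjusted p = 0.00862), Cstdc4 (−2.07, adjusted p = 0.0184) and the chemokine gene Ccl12 (−2.02, adjusted p = 0.0303). In the same fit macrophage genes were negative in 16 of 16 cases (median −0.58, adjusted p = 4.08e-12, adjusted p = 0.247 with an estimated correlation), and 9 of them fell adjusted over the list alone, so a lower macrophage content is not set apart from the last 3 of these calls. Over alternatives, Cstdc4 ran from −2.17 to −0.18 and Ccl12 from −2.15 to −0.04, each passing in 3 of 21. Lgals3 ran from −0.78 to −0.64 and passed in 5 of 22.

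**Figure D2:**
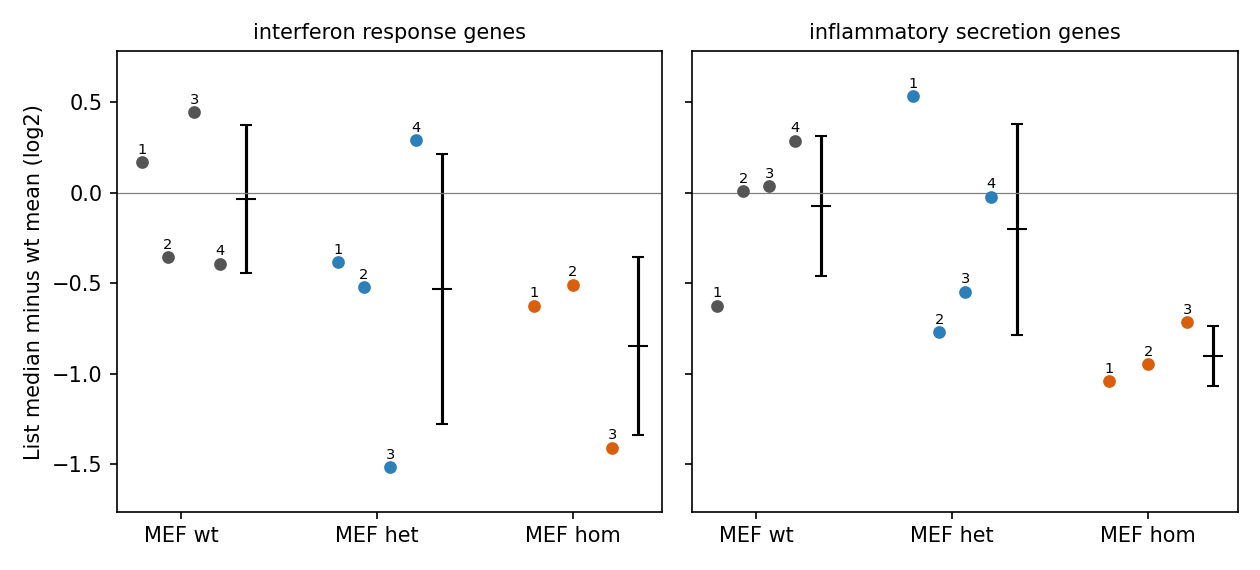
Median over the genes of the interferon response and inflammatory secretion lists on each MEF array, as log2 difference from the wt mean, with points numbered by replicate. Hom arrays lie at −0.62, −0.51 and −1.41 for interferon genes and at −1.04, −0.95 and −0.72 for inflammatory genes, and het 3 lies at −1.52 for interferon genes.

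In het against wt MEF the gene that changed in the fit of genotype alone was Pigt, part of the complex that attaches glycosylphosphatidylinositol anchors to proteins. Its log2 intensity was 9.13 ± 0.090 in het (SD, n = 4), 7.71 ± 0.16 in wt (n = 4) and 7.80 ± 0.11 in hom (n = 3). It rose 2.69-fold (1.43 ± 0.123 SE, limma adjusted p = 0.00323, range over 24 alternatives 3.97e-05 to 0.959). Interferon response genes were negative in 22 of 22 cases with a median of −0.53 (adjusted p = 3.28e-10, adjusted p = 0.830 with an estimated correlation), while the median of single het arrays ran from −1.52 in het 3 to 0.29 in het 4, and without het 3 it was −0.18. Fibroblast and extracellular matrix genes (24 of 28 positive, median 0.18, adjusted p = 0.00173) and p53 targets (21 of 23 positive, median 0.18, adjusted p = 0.00202) were higher. These 3 lists of 32 passed, each with adjusted p = 0.830 with an estimated correlation, and no member passed adjusted over the list alone. The fibroblast median was 0.0704 without wt 2, and that of p53 targets 0.0203 without het 3. Of 15125 probes, 1 rose and 0 fell in limma, with 225 at an unadjusted p under 0.05. Slide as a block left 0 probes (limma, 583 at an unadjusted p under 0.05) and 9 lists, 0 of which passed with an estimated correlation. Within slide 1, which held 3 wt and 3 het arrays, 0 probes and 9 lists did, with Pigt at 1.37 (adjusted p = 0.959). With the first principal component as a covariate 2 probes rose, that of Pigt and the dimmer of 2 probes of Hnrnpa0 at 1.38 (adjusted p = 0.0131).

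Hom against het MEF separates loss of both copies from loss of 1. Pigt fell by 1.33 ± 0.133 (SE, limma adjusted p = 0.0136, n = 3 and 4), and this was 1 of 15125 probes, with 242 at an unadjusted p under 0.05. As its level in hom was near that in wt, this call restates the higher level in the same het arrays. Glycolysis and hypoxia genes were negative in 20 of 20 cases, with a median of −0.32 (adjusted p = 2.33e-11, adjusted p = 0.388 with an estimated correlation). Adjusted over the list alone 2 of them fell, Pdk1 at −0.59 ± 0.14 and the phosphofructokinase gene Pfkl at −0.82 ± 0.22. Inflammatory secretion genes were negative in 18 of 19 cases (median −0.74, adjusted p = 2.33e-11, adjusted p = 0.388 with an estimated correlation), and Ptx3 fell adjusted over the list alone, at −0.78 ± 0.20. Interferon response genes (21 of 22 negative, median −0.37, adjusted p = 3.22e-05), immediate early genes (15 of 16 negative, median −0.33, adjusted p = 0.000864), imprinted genes (15 of 18 positive, median 0.20, adjusted p = 0.00276), smooth muscle genes (12 of 14 positive, median 0.10, adjusted p = 0.00594), cartilage and bone genes (9 of 9 positive, median 0.40, adjusted p = 0.0249) and Hox genes (16 of 22 positive, median 0.14, adjusted p = 0.0296) passed, each with adjusted p = 0.579 with an estimated correlation. Mylk, the myosin light chain kinase, rose adjusted over the smooth muscle list alone, at 0.51 ± 0.13. Macrophage genes (16 of 16 negative, median −0.37, adjusted p = 0.00147, adjusted p = 0.677 with an estimated correlation) and cholesterol biosynthesis genes (15 of 17 positive, median 0.46, adjusted p = 0.000636, adjusted p = 0.666 with an estimated correlation) made up the 10 lists. Without hom 3 the medians of the smooth muscle, interferon and cartilage lists were −0.0153, −0.21 and 0.22, and without het 2 that of macrophage genes was −0.0894. The medians were −0.15 for immediate early genes without het 3, 0.25 for cholesterol genes without het 4, 0.11 for imprinted genes without hom 2 and 0.0759 for Hox genes without hom 1.

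The Pigt call between hom and het MEF held in 12 of 23 alternatives (adjusted p from 3.50e-11 to 0.471) and was lost when any 1 of the 7 arrays was left out, while the difference stayed at −1.28 to −1.39. With slide as a block 0 probes passed in limma (885 at an unadjusted p under 0.05), and macrophage genes had a median of 0.66, a comparison of hom 1 and hom 2 with het 4 alone. Slide 4 held hom 1, hom 2 and het 4, and within it 8851 probes passed; het 4 lay opposite to both hom arrays on the first principal component. With that component as a covariate, 5 probes passed, among them the homeobox gene Alx4 at 0.83 (adjusted p = 0.0138) and Cdkn2a, which encodes cell cycle inhibitors, at −1.02 (adjusted p = 0.0345).

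In ESC the same numbers of different genotypes resembled each other: 9 of 9 pairs with the same number correlated at 0.367 to 0.773 after removal of group means, against −0.622 to 0.204 for different numbers, so fits with the replicate block are given as well. In hom against wt ESC, 0 of 14502 probes passed in limma without the block (1748 at an unadjusted p under 0.05), and by the brightest probe of each gene the 3 smallest p were those of Erdr1 at −1.77 ± 0.218 (adjusted p = 0.142), Pisd-ps3 at −2.04 ± 0.300 and the autophagy kinase gene Ulk1 at −0.82 ± 0.123 (both adjusted p = 0.145, n = 3 each). A dimmer probe of Timm21, at 0.88 ± 0.122, had an adjusted p of 0.145 as well. With the replicate block 599 probes passed, 271 higher and 328 lower (3649 at an unadjusted p under 0.05), of which 28 changed by at least 1 on the log2 scale.

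With the block, Spink1, a trypsin inhibitor, rose by 1.81 ± 0.314 (SE, n = 3 each, limma adjusted p = 0.0185) and the imprinted gene Nnat by 1.28 ± 0.170 (adjusted p = 0.00818). The carbonic anhydrase genes Car4 and Car2 rose by 1.16 and 1.12. Pou3f1, a transcription factor of the primed epiblast, rose by 1.06 ± 0.182. Pea15a (1.14), Sprr2k (1.13), Plac8 (1.09), Gbp2 (1.05), Lyz2 (1.05), Itm2a (1.04) and Ankrd1 (1.02) completed the 12 largest rises. Pisd-ps3 fell by 2.04 ± 0.245 (adjusted p = 0.00548), Erdr1 fell by 1.77 ± 0.185 (adjusted p = 0.00318) and the homeobox gene Nkx6-3 fell by 1.43 ± 0.250 (adjusted p = 0.0191). The gene of the receptor tyrosine kinase Kit fell by 0.96 ± 0.133 (adjusted p = 0.00906). The other 8 of the 12 largest falls, ranked without Mysm1, lay between −0.91 and −1.04 (Sorl1, Acss1, Cobl, Tex14, Pigh, Arhgap45, Pudp and Inpp5d). With slide as a fixed block in place of the replicate block, Gbp2 was at −1.28 and Ankrd1 at −0.31, but that fit links hom to wt only through the library labelled het 1, the 1 het array on the slide of the wt arrays. Some rises leaned on 1 array: without the block, Lyz2 was 0.25, Sprr2k 0.42 and Ankrd1 0.39 when hom 2 was left out, and Gbp2 was 0.53, Pou3f1 0.65, Car2 0.68 and Car4 0.73 when hom 3 was, and Pea15a was 0.75 when wt 1 was.

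Among gene lists 0 of 31 passed for hom against wt ESC without the block and 2 with it, 0 with an estimated correlation. Smooth muscle genes were positive in 9 of 11 cases with a median of 0.47 (blocked adjusted p = 0.00357, adjusted p = 0.775 with an estimated correlation), with 2 members rising over all genes and 7 adjusted over the list alone, among them Tagln at 0.85 ± 0.21 and Myl9, a myosin light chain, at 0.77 ± 0.19. The list was at −0.51 with slide as a fixed block, again through the library labelled het 1, and at 0.0227 without hom 2 and without the block. Primed epiblast and primitive streak genes were positive in 8 of 11 cases with a median of 0.19 (blocked adjusted p = 0.0316, adjusted p = 0.773 with an estimated correlation). Without hom 3 and without the block this median was 0.0754. Over all genes 2 of them rose, Pou3f1 and the transcription factor gene Sp5 at 1.01 ± 0.20, and 5 did adjusted over the list alone. Naive pluripotency genes did not pass as a list (28 genes, median −0.07, adjusted p = 0.527, blocked 0.215), though with the block 5 fell over all genes, and 1 rose and 9 fell adjusted over the list alone. Slide as a block gave 0 probes (limma, 991 at an unadjusted p under 0.05), no slide held both groups, and the replicate block with slide gave 51. Without replicate number 2 or number 3 the blocked count was 1 or 9, and without number 1 it was 1059.

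In het against wt ESC, 0 of 14502 probes passed in limma without the block (658 at an unadjusted p under 0.05), with the smallest p for Erdr1 at −1.64 ± 0.218 (adjusted p = 0.271), Pisd-ps3 at −1.89 ± 0.300 and Crtac1 at −0.81 ± 0.176. With the replicate block 37 passed, 28 higher and 9 lower (1986 at an unadjusted p under 0.05). The interferon-inducible GTPase gene Gbp2 rose by 1.47 ± 0.248 (adjusted p = 0.0425), Car4 by 1.16, Nnat by 1.15, Pea15a by 1.13 and Igfbp3, which binds insulin-like growth factors, by 1.11 ± 0.135 (adjusted p = 0.00665, n = 3 each). Those that fell were Pisd-ps3 (−1.89), Erdr1 (−1.64), Acss1 (−0.97), Hal (−0.87) and the signalling adaptor gene Gab1 (−0.49). Without het 3 and without the block, Gbp2 was 0.50, Car4 0.51, Igfbp3 0.65 and Hal −0.53, without het 2 Acss1 was −0.53, and without wt 1 Pea15a was 0.75. Within slide 2, which held 3 wt arrays and the library labelled het 1, 3 probes passed, and slide as a block, which rests on the same arrays for this comparison, gave 0 (limma, 308 at an unadjusted p under 0.05). The replicate block with slide gave 6. The blocked count was 0 in limma without number 3 (1797 at an unadjusted p under 0.05), 3 without number 2 and 243 without number 1.

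Without the block 5 of 31 lists passed for het against wt ESC, and 10 did with it. Targets of p53 were positive in 18 of 22 cases with a median of 0.27 (adjusted p = 0.00868, adjusted p = 0.670 with an estimated correlation, blocked 8.84e-06 and 0.165), and Ccng1, which encodes cyclin G, rose by 0.66 ± 0.10 with the block. Primed epiblast genes (9 of 11 positive, median 0.22, adjusted p = 0.0381), imprinted genes (16 of 19 positive, median 0.24, adjusted p = 0.0381) and smooth muscle genes (11 of 11 positive, median 0.36, adjusted p = 0.0381) were higher and S phase genes lower (20 of 24 negative, median −0.10, adjusted p = 0.0255), with estimated correlation adjusted p = 0.670, 0.670, 0.882 and 0.882. With the replicate block these had adjusted p = 0.00213, 0.00132, 1.70e-05 and 0.00213, each with adjusted p = 0.348 with an estimated correlation. The smooth muscle median was −0.10 without het 2 and 0.70 without wt 2, that of imprinted genes 0.11 and of S phase genes −0.0583 without het 2, and those of primed epiblast genes and p53 targets 0.0585 and 0.15 without het 3. With the block alone, fibroblast and extracellular matrix genes (21 of 22 positive, median 0.33, adjusted p = 4.15e-06), inflammatory secretion genes (9 of 11, median 0.34, adjusted p = 0.00806) and immediate early genes (8 of 11, median 0.17, adjusted p = 0.00587) passed, each with adjusted p = 0.409 with an estimated correlation. So did epithelium genes (12 of 14, median 0.14, adjusted p = 0.00132) and senescence genes (7 of 12, median 0.31, adjusted p = 0.0126), with adjusted p = 0.348 with an estimated correlation. The keratin genes Krt8, Krt18 and Krt19 rose adjusted over the epithelium list alone, at 1.21 ± 0.28, 1.37 ± 0.30 and 0.82 ± 0.18. Without the block, Krt8 was 0.45 and the immediate early median 0.0450 when wt 1 was left out, and Krt18 was 0.63 when het 3 was. Leaving out het 2 turned the inflammatory and senescence medians negative, and leaving out het 3 turned the epithelium median negative. With slide as a block, which sets the library labelled het 1 alone against wt, 1 list passed, and the medians of the fibroblast, smooth muscle, epithelium, senescence, inflammatory and immediate early lists were negative, from −0.05 to −0.27. The fibroblast list stood 1.91 above the wt mean in het 2 and −0.23 and −0.58 from it in the library labelled het 1 and in het 3, and without het 2 its median was −0.42.

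Between hom and het ESC 0 probes passed in limma either without the block (528 at an unadjusted p under 0.05) or with it (1573). The libraries labelled het 1 and hom 1, whose labels are in doubt, are part of both fits. By the brightest probe of each gene the smallest p were those of the catenin gene Ctnna1 at −0.42 ± 0.0939, Eef1akmt1 at 0.51 ± 0.125 and Pik3c2a, at least 1.09-fold lower as it was not above background on any hom array (adjusted p = 0.995 each, n = 3 each). Glycolysis and hypoxia genes were lower (18 of 20 negative, median −0.14, adjusted p = 0.0162, adjusted p = 0.924 with an estimated correlation, blocked 0.00403 and 0.755). Mitochondrial respiratory chain genes were higher (39 of 53 positive, median 0.07, adjusted p = 0.0162, adjusted p = 0.967 with an estimated correlation, blocked 0.0123 and 0.755). With the block, fibroblast and extracellular matrix genes (22 of 22 negative, median −0.18, adjusted p = 0.000887, adjusted p = 0.771 with an estimated correlation) and p53 targets (18 of 22 negative, median −0.13, adjusted p = 0.0330, adjusted p = 0.755 with an estimated correlation) were lower as well, which made 4 lists against 2. Slide as a block gave 0 probes (limma, 903 at an unadjusted p under 0.05) and 7 lists, and within slide 3, which held het 2, het 3 and 3 hom arrays, 7 lists passed. With slide as a block and an estimated correlation 0 lists passed. Without the block the fibroblast list had a median of 0.52 when het 2 was left out, and it was positive as well when hom 3 was. Targets of p53 were at 0.0167 without the library labelled hom 1, glycolysis genes at −0.0891 without hom 2 and respiratory chain genes at 0.0295 without het 3.

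Without the libraries labelled het 1 and hom 1, chosen after seeing the data, the blocked counts were 1073 probes for hom against wt (553 higher, 520 lower), 245 for het against wt (175 higher, 70 lower) and 260 for hom against het (146 higher, 114 lower), with 2 residual degrees of freedom. Without the block they were 3, 0 and 1 in limma, with 2011, 989 and 922 at an unadjusted p under 0.05. The Y-linked gene Eif2s3y was detected in het 2 and het 3, and not in hom 2, hom 3 or the wt arrays. In hom against het and het against wt, genotype thus cannot be told apart from a difference in sex chromosomes. Hom against wt is not free of this either, though neither group showed Eif2s3y. The median of X-linked genes lay above the wt mean by 0.33 in hom 2 and 0.37 in hom 3. Xlr4a was at least 13.6-fold higher in hom than in wt (blocked adjusted p = 5.16e-08) and higher by 3.92 than in het, where it was above background on 1 of 2 arrays and the value is near the floor. That p-value is no test of the hom genotype as labelled, as the fit leaves out the library labelled hom 1, where Xlr4a was low. On single arrays Xlr4a was 9.07 in the library labelled het 1, 8.81 in hom 2 and 8.58 in hom 3, and 4.97 in the library labelled hom 1. The X-linked homeobox genes Rhox6 and Rhox9 rose by 1.62 and 1.61 in hom against het. In het against wt, Krt18 rose by 1.96, Krt8 by 1.76 and the skeletal actin gene Acta1 by 2.02, while the library labelled het 1, which slide as a fixed block sets alone against wt, had Krt18 at −0.85, Krt8 at −1.43 and Acta1 at −0.60. In the same comparison naive pluripotency genes were lower as a list (23 of 28 negative, median −0.26, adjusted p = 8.79e-06, adjusted p = 0.288 with an estimated correlation). They were 1 of 15 lists that passed there, 13 of them higher, among which were smooth muscle (median 0.48, adjusted p = 1.87e-09), fibroblast (0.43, adjusted p = 2.51e-10), skeletal muscle (0.52, adjusted p = 0.00670) and primitive endoderm genes (0.37, adjusted p = 0.0159), and 0 of the 15 passed with an estimated correlation.

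Medians over whole chromosomes differed between single ESC arrays. The median of 124 X-linked genes lay above the wt mean by 0.24 in the library labelled het 1, 0.33 in hom 2 and 0.37 in hom 3. In the library labelled hom 1 it was 0.01, in het 2 −0.04 and in het 3 0.04. For the first 3 of these, 0 of 10000 random gene lists of the same size were as high. The Y-linked gene Eif2s3y was detected in het 2 (5.41), het 3 (5.70) and the library labelled hom 1 (5.45), and not in the library labelled het 1 (4.19), hom 2 (4.2), hom 3 (4.33) or the wt arrays. Uty, also Y-linked, read near the floor and did not part the arrays in this way. It was detected in the libraries labelled het 1 (4.90) and hom 1 (4.99), in het 2 (4.93) and in het 3 (4.88). Arrays where it missed the limit included hom 2 at 4.895 and wt 3 at 4.91. The median of 276 genes on chromosome 8 was lower than in wt in the 6 het and hom arrays, from −0.17 to −0.26, and 0 of 10000 random lists were as low in any of them. Wt 1 at 0.10 and wt 3 at −0.07 also lay outside the random lists. As all values are set against the wt mean, higher chromosome 8 expression in the wt arrays would give the same pattern as lower expression in het and hom. Differences of single genes on chromosomes X and 8 in ESC were not corrected for these shifts.

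**Figure D3:**
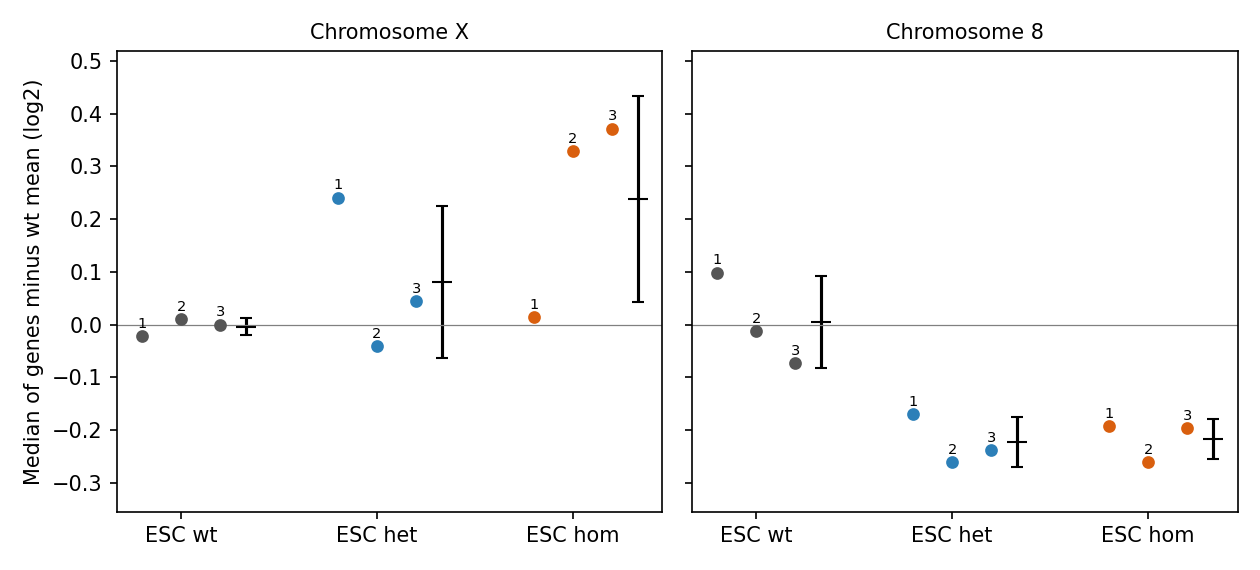
Median log2 difference from the wt mean over the genes of chromosomes X and 8 on each ESC array, with points numbered by replicate. The library labelled het 1, hom 2 and hom 3 lie at 0.24, 0.33 and 0.37 for X, and het and hom arrays lie at −0.17 to −0.26 for chromosome 8.

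Hom and het differences from wt share their wild-type arrays, which alone makes them correlate. In MEF they correlated across probes at r = 0.514 (covariance 0.0281), against 0.464 (0.0509) in 100 simulations of unchanged groups, and at 0.00559 on average over 6 ways of giving each difference its own 2 wt arrays (−0.694 to 0.324). In ESC r was 0.718 (covariance 0.0439), against 0.501 (0.0304) in simulations, and 0.0130 was the simulated covariance with the replicate block. Of the probes called with the block, 20 rose in both (0.523 under independence) and 9 fell in both (0.204 under independence), an expectation that leaves out the shared wild-type arrays, so the excess is not a test of a shared genotype effect. These figures are across genes, which are not independent replicates.

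Whether the genotype difference itself differs between ESC and MEF was tested as an interaction over 17067 probes. In limma 0 probes passed for hom against wt (884 at an unadjusted p under 0.05) and 0 for het against wt (460). By the brightest probe of each gene the smallest p for hom were those of Plac8 at 1.96 ± 0.364 and the germline gene Taf7l (adjusted p = 0.307 each) and Sec63, part of the protein translocation machinery, at 1.10 ± 0.223, and for het those of Pigt at −1.44 ± 0.249 (adjusted p = 0.33), Sec63 at 0.99 and Hps5. No size is given for Taf7l, not above background in MEF or wild-type ESC, or for Hps5, not above background in ESC. The Mysm1 difference was −0.02 ± 0.647 for hom and −0.83 ± 0.625 for het. Interferon response genes differed as a list for hom (median 0.80) and so did inflammatory secretion genes (median 0.90), with adjusted p = 4.56e-11 and 1.03e-06. In the wild type, 10 of 22 and 8 of 19 of these genes were above background in only ESC or only MEF. A gene below background in a cell type can show no genotype difference there, so these list interactions can restate the fall in MEF. With an estimated correlation 0 of 33 lists passed in either interaction. Hom against wt differences of the cell types correlated at r = −0.0267 over 12831 probes tested in both.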

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

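The counts over other splits and the tests of every pattern weighed here were chosen after the results they measure had been seen, while the single values and interactions followed rules set beforehand. Tests of the libraries labelled ESC het 1 and hom 1 were changed several times after their values were known. The test of varying cultures first read the position of hom 1 alone (0.421), then X-linked genes, then autosomal genes as well. A looser form of the exchange test was also run. It asked only that het 1 lie above hom 1 on autosomal genes and added Eif2s3y, whose values were already known; the exchange met it, and the form was withdrawn in favour of the stricter one. The test of the hom genotype for X-linked genes first counted against genotype and was then made to depend on an exchange of labels being ruled out. The test of macrophage content was written with its values known and counts against that explanation only if macrophage genes are also not lower in hom with the first component as a covariate. By the gap between arrays alone, 0.694 with an SD of 0.167 among hom arrays, inflammatory genes would have counted against it.

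The median log2 intensity of p53 targets in MEF wt 3 was 7.86, apart from the other wt arrays at 8.12 to 8.16. Erdr1 in MEF het 1 was 4.31, against 10.75 to 11.74 in the other het arrays. These were 2 of 50 groups tested, and chance sets about 1 in 20 apart. That rate does not weigh the size of a gap. Erdr1 differed widely between MEF arrays of the same genotype, which limits reading its fall in het and hom ESC as an effect of genotype.

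For hom against wt, 7 lists differed between ESC and MEF by the interaction itself: interferon response (adjusted p = 4.56e-11), inflammatory secretion (adjusted p = 1.03e-06), cartilage and bone (adjusted p = 0.0203), macrophage (adjusted p = 0.0233), cholesterol biosynthesis (adjusted p = 0.0250), MHC class I (adjusted p = 0.0260) and primed epiblast and primitive streak genes (adjusted p = 0.0265). For het against wt, 4 differed: interferon response (adjusted p = 6.10e-08), primed epiblast (adjusted p = 0.0295), smooth muscle (adjusted p = 0.0295) and imprinted genes (adjusted p = 0.0480). None of the 11 passed with an estimated correlation. Many interferon, inflammatory and macrophage genes were above background in only ESC or only MEF of the wild type, among them 11 of 16 macrophage genes. For these lists the interaction can therefore restate the MEF difference.

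Other splits of the arrays were counted for each comparison. For MEF hom against wt, 2 of 35 splits gave as many probes as the real 1, and 8 of 35 as many lists as the real 12 (highest other 15), so chance is not excluded for either count. The other split, hom 3 with wt 2 and wt 3, gave 5627 probes, which points to a structure among the arrays that follows the first principal component. For het against wt, 2 of 35 gave as many probes as the real 1 and 29 of 35 as many lists as the real 3, and het 1, het 2, wt 1 and wt 4 against the rest gave 8117 probes. For hom against het, 2 of 35 gave as many probes as the real 1 and 15 of 35 as many lists as the real 10, and hom 3, het 3 and het 4 against the rest gave 3574 probes. With the first component as a covariate, the real counts of 4 and 2 probes for hom and het against wt were reached by 1 of 35 splits each, the real one (highest others 1 and 0), and that of 5 for hom against het by 2 of 35 (highest other 33). In ESC the 10 splits are too few for a share under 0.05: real counts of 0 probes stood beside highest others of 0, 0 and 4, matched by 10 of 10 splits each, and 0, 5 and 2 lists beside 10, 15 and 12, matched by 10, 8 and 7. With the replicate block the 4 splits that part every pair are too few as well, with real counts of 599, 37 and 0 beside 0, 0 and 34, matched by 1, 1 and 4. The 34 came from the split that exchanges het 1 and hom 1. A real count of 0 is reached by every split, so these shares test nothing there or for the interactions, where it was 100 of 100 drawn splits with highest others of 2441 and 5197, which again points to structure among the arrays.

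Mysm1 was 4.45 in the library labelled ESC het 1 and 6.47 in that labelled hom 1, out of order with the other arrays. A dim array is argued against, since 30.4% of probes were detected on het 1, within the range of the other ESC arrays. An exchange of the labels remains open: on the axis from het (0) to hom (1) set by the other arrays, het 1 lay at 0.744 and hom 1 at 0.421, but on autosomal genes alone they lay at 0.657 and 0.501, so hom 1 missed the predicted side. For scale, het 2 and het 3 lay at 0.279 and 0.346 and hom 2 and hom 3 at 0.55 and 0.735. Each was placed on an axis from the other pair with 500 probes, sex chromosomes included. Mysm1 varying between correctly labelled cultures also remains open. X-linked genes were higher in het 1 than in hom 1 by 0.227, against −0.369 and −0.327 for numbers 2 and 3. Xlr4a was 9.07 in het 1 and 4.97 in hom 1. Both go against varying cultures. The autosomal order was reversed as well, with het 1 (0.657) above hom 1 (0.501), but hom 1 missed the side that the test asked for. Eif2s3y was detected in the library labelled hom 1 and not in that labelled het 1, as an exchange would give, but lines per genotype were not stated and the labels could not be decided from these arrays. Uty, Y-linked but near the floor, was detected in both libraries.

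Interferon response and inflammatory secretion genes were lower in MEF hom, with medians of −0.87 and −0.95, and the first principal component is argued against as the whole cause, since medians with it as a covariate were −0.892 and −0.985. With members below background in one group at their bound, these were −0.79 and −0.60, against −0.70 and −0.74 without the covariate. As small a list p was given by 4 of 35 splits for interferon genes, so chance is not excluded there, and by 1 of 35, the real one, for inflammatory genes. With slide as a fixed block the medians were −1.75 and −1.20, but a single array of another genotype shared a slide with hom, so slide and genotype cannot be told apart. A lower macrophage content remains open: wt 2, wt 3 and het 4 had macrophage medians below every hom array, yet lay above the highest hom array by at least 0.153 for interferon and 0.694 for inflammatory genes, while with the component as a covariate macrophage genes were lower in hom (median −0.58). The hom genotype and the sex of the animals remain open and may each contribute; this pair of lists was chosen for weighing, in place of macrophage genes, after values of single arrays were seen.

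X-linked genes were higher in ESC hom 2 and hom 3. The shift was shared by most of the X-linked genes measured, with at least 80.6% of them above their wild-type mean in both arrays. The hom genotype remains open: the median in the library labelled hom 1 was 0.0137 and that in het 1 was 0.240, which go against genotype as labelled, but with these 2 labels exchanged all 3 hom arrays and no het array would be high. A difference of line or passage remains open and could not be told apart from genotype, because the labels give no lines and the library labelled het 1 is itself in doubt. Among het and hom arrays, X-linked genes were high where the Y-linked gene Eif2s3y was not detected (the library labelled het 1, hom 2 and hom 3). They were near wild type where it was detected (het 2, het 3 and the library labelled hom 1). The wt arrays, which set the baseline, also lacked it. A difference in sex chromosomes between the cells therefore remains open as well. It rests on Eif2s3y alone, as Uty, Y-linked but near the floor, was also detected in the library labelled het 1. Copy number of the X chromosome was not measured.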

How the results depend on the processing

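Principal components as covariates, leaving out the libraries labelled ESC het 1 and hom 1, the replicate block with slide and the replicate block without a number were chosen after seeing the data. The other alternatives were set beforehand. Over alternatives, counts of probes stayed within 1.5 times the reported count in 140 cases and moved beyond it in 54, and counts of lists in 101 and 54. The reported counts of probes were 1 in MEF comparisons and 0 in ESC and interactions. A count of 0 that stayed at 0 is among the 140, so that number says little of stability. Single named genes reversed in 32 cases and single lists in 28. Without reversing, single lists no longer passed in 185 cases and newly passed in 59. The fall of Mysm1 in MEF hom kept its direction in 21 of 21 alternatives that tested its probe, and passed in 18. Where a result changed, the cause was not tested, unless a reason is given below. Fewer arrays or fewer degrees of freedom were left by within-slide fits and by leaving arrays out. Signal over background limits dim genes: 28.5 to 31.8% of probes were detected on an array, and 3 of 4 Mysm1 probes were not above background.

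With an estimated correlation, 0 lists passed in MEF hom against wt, het against wt and hom against het, and 0 in ESC het against wt and hom against het. At adjusted p under 0.01, MEF hom against het gave 0 probes. Median scaling gave 5 lists in MEF het against wt, 0 probes in MEF hom against het and 1 list in ESC hom against wt. With all 20 arrays together, MEF hom against wt gave 0 probes and ESC hom against wt 7. With no filter, MEF hom against het gave 0 probes, ESC hom against wt 1 probe and 1 list, and ESC het against wt 1 probe. With probes detected on all arrays, MEF hom against wt gave 0 probes, ESC het against wt 2 lists and ESC hom against het 1 list. In MEF this filter removed the Mysm1 probe itself, which was not above background in hom 3. The mean over the probes of a gene gave 2 lists in ESC het against wt, and normexp per array 3. Array weights gave 2 probes in MEF hom against wt, 148 in MEF hom against het, 10 lists in MEF het against wt with p53 targets at −0.10, 3 lists in ESC het against wt, and 18 probes in the interaction for hom. These counts of 0 probes are from limma, with 387, 225 and 242 MEF probes at an unadjusted p under 0.05 in the reported fits.

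Fitting slide as a fixed block, MEF hom against wt, het against wt and hom against het gave 0, 0 and 0 probes in limma (2241, 583 and 885 at an unadjusted p under 0.05), and MEF het against wt 9 lists. List medians reversed in MEF hom against wt for p53 targets (−0.40) and macrophage genes (1.27), and in hom against het for smooth muscle (−0.16) and macrophage genes (0.66). These MEF comparisons of hom rest on het 4, the 1 array of another genotype on a slide with hom. In ESC the slide block sets the library labelled het 1 alone against wt and links hom to wt through it, so for het against wt it repeats the comparison within slide 2 and is no separate check. In ESC the fixed slide block gave 1 list in het against wt and 7 in hom against het. In ESC hom against wt it put smooth muscle genes at −0.51, Gbp2 at −1.28, Ankrd1 at −0.31 and Actg2 at −0.17. In ESC het against wt it put fibroblast genes at −0.23, smooth muscle at −0.27, epithelium at −0.21, senescence at −0.19, inflammatory secretion at −0.0488 and immediate early genes at −0.11, with Gbp2 at −0.0857, Acta1 at −0.60, Krt18 at −0.85, Krt8 at −1.43 and Pmp22 at −0.41. Slide as a random block gave 2 probes in MEF hom against wt. Within slide 1, MEF het against wt gave 0 probes and 9 lists. Within slide 4, MEF hom against het gave 8851 probes, with smooth muscle genes at −0.18 and macrophage genes at 0.66. Within slide 2, ESC het against wt gave 3 probes and 1 list, with fibroblast genes at −0.23, smooth muscle at −0.26, epithelium at −0.21, senescence at −0.19, inflammatory secretion at −0.0490, immediate early genes at −0.11, Gbp2 at −0.0869, Acta1 at −0.60, Krt18 at −0.86, Krt8 at −1.44 and Pmp22 at −0.39. Within slide 3, ESC hom against het gave 7 lists.

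The replicate block gave 0, 0 and 0 probes in MEF hom against wt, het against wt and hom against het (limma, 365, 186 and 281 at an unadjusted p under 0.05). In ESC it gave 599 probes and 2 lists for hom against wt, 37 and 10 for het against wt, and 4 lists for hom against het. With slide as well, it gave 51 probes for hom against wt with Gbp2 at −0.17, 6 probes and 3 lists for het against wt with Pmp22 at −0.32, Rhox6 at 0.97 and Rhox9 at 0.76, and 8 probes and 5 lists for hom against het. Without number 1 the block gave 1059 probes and 2 lists, 243 and 15, and 240 and 6 in the same order of comparisons. Without number 2 it gave 1 probe and 1 list, 3 and 8, and 1 list for hom against het, with Mysm1 at 0.0716 and Xlr4a at −0.0243. Without number 3 it gave 9 probes and 2 lists for hom against wt, 0 probes for het against wt (limma, 1797 at an unadjusted p under 0.05) and 9 lists for hom against het, with Mysm1 at 0.37, Xlr4a at −0.18 and Heph at −0.15. Without the libraries labelled het 1 and hom 1, ESC gave 3 probes for hom against wt, 10 lists for het against wt, and 1 probe and 0 lists for hom against het. With the block besides, it gave 1073 probes and 2 lists, 245 and 15, and 260 and 5.

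With the first principal component as a covariate, MEF hom against wt, het against wt and hom against het gave 4, 2 and 5 probes. With the first and second they gave 128, 21 and 38, with S phase genes at 0.0363 in hom against wt. With the first component of group-centred values they gave 431, 2 and 203, a setting that understates the error because the component is drawn from the residuals. The correlation of hom and het differences in MEF was 0.00559 with the wild-type arrays split.

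Leaving out each replicate in turn, MEF hom against wt gave 7 to 12 lists, with medians from −0.40 to 0.00101 for S phase genes and −0.68 to 0.0669 for macrophage genes, het against wt 2 to 10, and hom against het 0 probes without any single array and 6 to 14 lists. ESC het against wt gave 1 to 10 lists and hom against het 0 to 7. In ESC het against wt, medians ran from −0.42 to 0.84 for fibroblast genes, −0.0732 to 0.39 for epithelium, −0.0840 to 0.38 for senescence −0.28 to 0.79 for inflammatory secretion and −0.10 to 0.70 for smooth muscle genes, reversed without het 3 for epithelium and without het 2 for the others. The senescence list also turned by its test without wt 1. In ESC hom against het they ran from −0.76 to 0.52 for fibroblast genes, reversed without het 2 or hom 3, from −1.12 to 0.0110 for Mysm1, reversed without hom 3, and from −1.94 to 0.23 for Krt8, reversed without het 3 or the library labelled hom 1. The Mysm1 interaction for hom ran from −0.48 to 0.39, and the interaction for het gave 0 to 1 probes.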

Other observations

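MEF arrays of wt and het included some with an X-inactivation marker and some with a Y-linked marker, while hom arrays had the first on 2 of 3 and the second on none. Xist, the RNA that silences an X chromosome in female cells, was detected on the arrays of wt 2, wt 4, het 1, hom 1 and hom 2, at 5.86 to 6.77 over both probes. Eif2s3y, on the Y chromosome, was detected in wt 1 (5.89), het 2 (5.75) and het 3 (5.63). Neither was detected at the set limit in wt 3, het 4 or hom 3, where Eif2s3y read 4.96, 4.77 and 4.74.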
